A study of Rattus norvegicus with 8 samples.

How the data were processed

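RNA was measured in scraped epithelium of the urinary bladder and of the ureter from 6-week-old female Fischer CDF rats. Per the labels' protocols, total RNA was isolated from the scraped cells, polyadenylated RNA was captured with oligo(dT), and libraries made with a total RNA kit were sequenced on an Illumina HiSeq instrument. The design text names 4 rats of 1 litter, and the labels give 4 bladder and 4 ureter libraries, all with the same batch date. Each library is called here by its tissue and the number in its label (1, 3, 4 or 5).

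The deposited count table holds whole-number read counts for 28546 genes in the 8 libraries. Per the submitters' processing notes, bcl2fastq 2.20, STAR 2.4.5a, featureCounts, Subread 1.4.6-p3, DESeq2, R 3.3.0 and the rat genome build rn6 were used; the notes give these names without saying which step each served. The counting settings, strand included, and the gene annotation are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, could be divided between genes. A deposited table of normalized values (a signal in the sense of a count divided by a size factor) was tested against the counts: 100.0% of its values lay within 0.02 of the count divided by the median-ratio size factor computed here. The deposited FPKM table was tested over 6478 genes with high values, where FPKM was the normalized count times 1 constant per gene, with a highest-to-lowest ratio of at most 1.0018 among the 8 libraries. Both derived tables therefore carry the same counts, and the count table was used for the main tests. No coordinates are given, because the RefSeq gene table used for names is of the assembly GRCr8, not rn6; 17169 of the 28546 symbols occur in it.

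Total counts were 21740582, 18561742, 19751402 and 15092426 in bladder libraries 1, 3, 4 and 5, and 28991057, 23361079, 18340560 and 18672890 in ureter libraries 1, 3, 4 and 5; 8861 genes had 0 counts in all. A count of 0 in a library allows a level of up to 3 counts, which is 0.103 CPM (read counts scaled to library size) in the deepest library and 0.199 CPM in the shallowest. Folds against a tissue with 0 counts in all of its libraries are lower bounds against a floor of 3 counts over the group, and ratios against 1 to 3 counts have an exact 95% binomial interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a tissue agreed within sampling noise: chi-square per degree of freedom, over genes with at least 20 counts in both, was 22.52 to 129.22.

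Genes were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, default filter on low counts, tissue as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The log2 fold change is ureter minus bladder, so positive values are higher in ureteral urothelium. CPM values use TMM-scaled library sizes and are given as mean ± SD over 4 libraries; ± after a log2 fold change is its standard error, computed as the absolute log2 fold change over the square root of the F statistic. Counts were simulated from these libraries' means and spread (12858 genes), with 50 genes changed at each fold. The fit recovered 16% of genes changed 1.5-fold, 68% at 2-fold, 98% at 4-fold and 100% at 8-fold, and 4.7% of its calls were false. Fewer genes changed there than passed in the real libraries, which makes the adjusted threshold stricter. These shares may thus be too low for the real comparison. The median log2 fold change of all tested genes was -0.004, and size-factor, upper-quartile or no scaling moved it by at most 0.004.

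A set of 35 gene lists (programs of the urothelium, its development and its stress responses, and marker lists of other cell types a scraping could hold) was fixed, with the rule for named genes below and the settings of the main test, before the data were examined, and 589 of its 614 genes occur in the table. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01). Beside it stand camera with an estimated correlation, and fry, which tests whether a list's genes move on balance 1 way and does not compare the list with other genes. A list planted at 2-fold in simulated counts was found by all of these tests, with 0 unchanged lists called. The simulated genes were independent of each other, so the 0 says nothing about calls that correlated genes cause. In other splits of the real libraries, camera at the preset correlation called up to 16 lists. Member counts are given over all genes tested and adjusted over the list alone.

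The genes named in the text were chosen by that rule. It takes the 10 genes with the largest fold change in each direction among those past the threshold with a mean of at least 10 CPM in the higher tissue, no overlap between the tissues' libraries and a symbol that is not provisional. It adds up to 2 members per list and direction with the smallest adjusted p among those past the threshold, and a set of urothelial genes named whatever their values (Upk1a, Upk1b, Upk2, Upk3a, Upk3b, Krt5, Krt14, Krt20, Tp63, Shh, Foxa1, Pparg, Gata3, Hoxa13, Hoxd13, Pax2 and Pax8). This gave 98 genes, of which 97 were tested and some are not reported here; genes outside it are said to be chosen after their values were seen.

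The numbers 1, 3, 4 and 5 occur once in each tissue and the design text names 4 rats, so same-numbered libraries were taken as the same rat; the labels do not say so in words. The deviations of same-numbered libraries from their tissue means correlated over genes by 0.04, 0.056, 0.145 and 0.357 for rats 1, 3, 4 and 5. The fit with the rat as a block was an alternative to the main test. Other alternatives chosen in advance were DESeq2 1.42.0, limma-voom, other scalings, no filter and a stricter filter on low counts (at least 1 CPM in 4 libraries), limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 0.5 in at least 4 libraries, limma-trend on log2(FPKM + 1) without a filter, and leaving out each library or each rat. Marker scores of nerve and glia, smooth muscle or fibroblasts as a covariate, and bladder library 1 alone against the 4 ureter libraries, were added after the data were seen. Fold changes on a log2(FPKM + 1) scale understate changes of low genes. Tests of single values between tissues are exact two-sided permutation tests (scipy 1.17.1).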

Results

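Gene expression was compared between the urothelium of the urinary bladder and that of the ureter, the epithelia that line these organs, in 6-week-old female Fischer CDF rats. The design text assigns the bladder epithelium to the endoderm and the ureteral epithelium to the mesoderm, and the comparison asks which genes the 2 groups express at different levels. Each tissue had 4 libraries from 4 rats of 1 litter, so p-values measure the spread among littermates. Total counts ranged from 18340560 to 28991057 in ureter and from 15092426 to 21740582 in bladder libraries (n = 4 each; two-sided exact permutation p = 0.257). Mitochondrial genes took 6.62 ± 1.76% of counts in ureter and 8.60 ± 1.00% in bladder libraries (mean ± SD, n = 4 each; exact permutation p = 0.114). The 10 most abundant genes took 8.60 ± 1.66% and 11.3 ± 1.28% (n = 4 each; exact permutation p = 0.0571).

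Ureter libraries held mRNA of the nephric duct transcription factors Pax2, Pax8 and Emx2, which stood at or near 0 in bladder libraries. Bladder libraries held low levels of the posterior Hox genes Hoxb13, Hoxd13 and Hoxd11, which stood at or near 0 in ureter libraries. Bladder libraries held more mRNA of the terminal keratin Krt20, of Krt4 and of the uroplakin Upk2, the latter a component of the apical plaques of umbrella cells. Ureter libraries held more of the basal keratin Krt14, of the mitotic genes Top2a and Plk1, and of Eng, a coreceptor for TGF-beta family ligands, at 414 ± 39.7 CPM against 9.78 ± 2.33 CPM (n = 4 each). Of 12992 genes tested, 1513 (11.6%) differed by edgeR at an adjusted p under 0.05: 740 were higher in ureter and 773 in bladder, and 305 and 371 of these were at least 2-fold apart. The libraries of the tissues did not overlap for 18.6% of all tested genes, against 2.86% by chance. They did not overlap for 1400 of the 1513 genes (92.5%), and 1473 went the same way in all 4 rats. Both counts follow in part from the choice of these genes by the same libraries. The counts depended on single libraries. They were 394 higher in ureter and 452 in bladder without bladder library 3, 433 and 487 without bladder 5, 458 and 462 without ureter 1, and 342 and 412 without ureter 4, where 189 genes were at least 2-fold higher in ureter. Without bladder library 1, 701 genes were at least 2-fold higher in bladder. With the nerve marker score as a covariate, an alternative chosen after the data were seen, 137 and 210 genes passed. That score was 4.10 to 5.73 in bladder libraries 3, 4 and 5, 1.402 in bladder library 1 and 1.52 to 2.58 in ureter libraries. It thus parts poorly from tissue, and a call lost with it need not mean a smaller difference.

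Genes of the nephric duct and ureteric bud, the embryonic structures from which the ureteral epithelium grows, were higher in ureter as a group. Of 12 tested members 7 were higher in ureter and 0 in bladder (7 and 1 adjusted over the list alone; camera adjusted p = 1.506e-09, and 0.0146 with an estimated correlation). With the rat as a block 6 members passed. The smooth muscle score as a covariate left 4 members and a median log2 fold change of 0.475, against 0.847 without it. The nerve score left 5 members and a median of 1.286. The fibroblast score gave 6 members higher in ureter and 1 in bladder. Pax8 reached 33.5 ± 7.88 CPM in ureter and 0.727 ± 0.486 CPM in bladder (log2 fold change 5.57 ± 0.42, edgeR adjusted p = 0.000146, n = 4 each). Emx2 was at 16.1 ± 4.31 and 0.202 ± 0.248 CPM (6.22 ± 0.62, edgeR adjusted p = 0.000375; log2 fold change 7.65 without bladder library 4). Pax2 had 283 counts over the ureter libraries, 3.09 ± 0.702 CPM, and 0 in every bladder library, at least 79.3-fold higher in ureter (edgeR adjusted p = 0.000584). Etv4, a transcription factor downstream of Ret and FGF signalling, was 2.32-fold higher in ureter, and Wnt7b 1.41-fold. Wnt7b lost its call without bladder library 3 or 5 (edgeR adjusted p up to 0.0565 over the fits without 1 library). Gata3, which acts in the nephric duct and in urothelium alike, was at 207 ± 44.4 and 193 ± 24.5 CPM and did not differ past the threshold (edgeR adjusted p = 0.72). The list median is 0.85 on the log2 scale, also with Pax2 set at its bound. Of the 6 tested endoderm transcription factors only Foxa1, a factor of endodermal epithelia, passed, and it was higher in ureter (133 ± 18.5 against 77.4 ± 15.7 CPM, log2 fold change 0.78 ± 0.16, edgeR adjusted p = 0.0139). That list as a group was not past the threshold (camera adjusted p = 0.376). Under the fit with the rat as a block 2 members passed toward ureter, with a median log2 fold change of 0.339 against 0.038. With the nerve score as a covariate 0 members passed, at a median of 0.222.

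Hox genes, which mark position along the body axis, went both ways. All 6 tested posterior members (paralogues 9 to 13) passed, 4 of them higher in bladder and 2 in ureter, the same counts adjusted over the list alone. Hoxb13 had 299 counts in bladder, 4.06 ± 1.25 CPM, and 0 in every ureter library, at least 119-fold higher in bladder (edgeR adjusted p = 0.000517, n = 4 each). Hoxd13 had 123 counts in bladder and 1 in ureter, a ratio of 146 (95% interval 25.8 to 5829), and Hoxd11 had 88 and 1, a ratio of 105 (95% interval 18.3 to 4183). Without the library that held the single count, ureter 1 for Hoxd13 and ureter 3 for Hoxd11, their log2 fold changes went from -6.59 to -8.00 and from -6.14 to -7.58. Hoxa13 was not tested because of low counts, with 6, 8, 19 and 1 in bladder libraries 1, 3, 4 and 5 and 1, 1, 2 and 0 in the ureter libraries. The other 2 posterior members went the other way: Hoxd9 was at 23.4 ± 3.37 CPM in ureter and 7.00 ± 1.92 CPM in bladder (log2 fold change 1.74 ± 0.21, edgeR adjusted p = 0.00104), and Hoxb9 was 2.02-fold higher in ureter. Among the 11 tested anterior and middle members 4 were higher in ureter and 1 in bladder (5 and 2 adjusted over the list alone). That list did not pass (camera adjusted p = 0.258), but it did with the stricter filter (0.027), with the nerve score as a covariate (0.039) and for bladder library 1 alone (0.00535; 0.00535 to 0.945 over 19 alternatives). Hoxd3 was at 4.65 ± 1.78 CPM in ureter and 0.321 ± 0.243 CPM in bladder (3.84 ± 0.56, edgeR adjusted p = 0.00294; log2 fold change 4.43 without bladder library 4). Hoxd8 was 2.64-fold higher in ureter. Hoxa3 went the opposite way with 118 counts in bladder and 3 in ureter, a ratio of 46.8 (95% interval 15.6 to 230.3), and its log2 fold change went from -5.36 to -6.13 without ureter library 1. The posterior list was lower in ureter by camera (adjusted p = 0.00475), with adjusted p = 0.327 with an estimated correlation and 0.413 with the stricter filter on low counts (0.00076 to 0.413 over 19 alternatives). Its median log2 fold change was -4.57, also with Hoxb13 set at its bound.

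**Figure D1:**
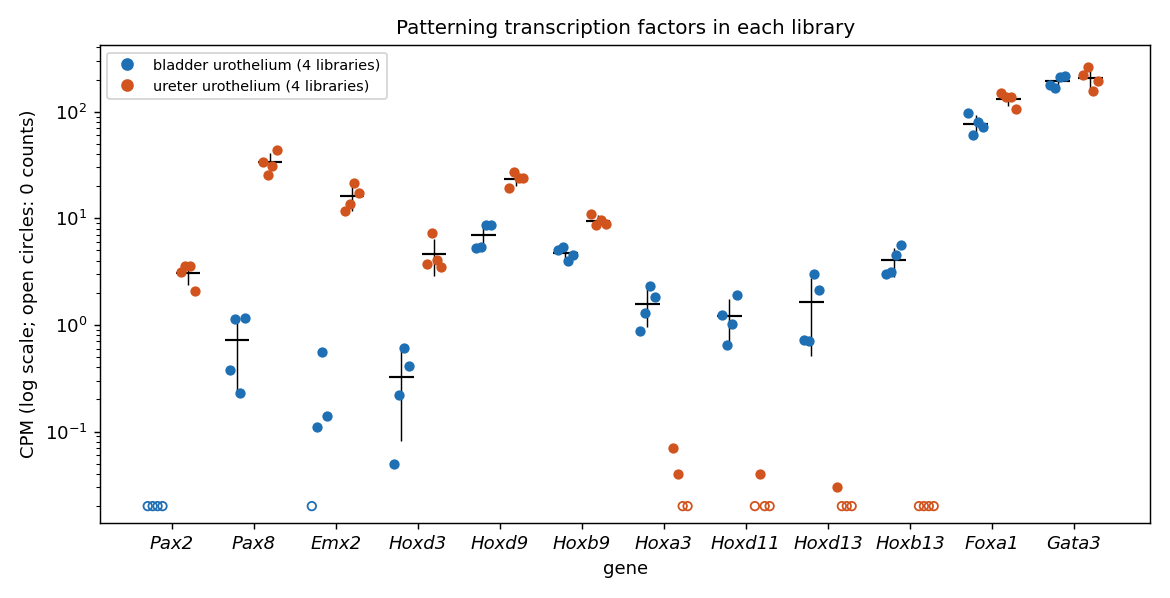
CPM of 12 transcription factor genes in each of the 8 libraries on a log axis, with bladder in blue and ureter in orange; open circles are libraries with 0 counts, placed at the bottom of the axis. Horizontal lines are means and vertical lines SD over 4 libraries, drawn where no library is at 0 counts. Pax8 lies at 25.3 to 44.1 CPM in ureter and 0.23 to 1.16 CPM in bladder libraries, whereas Hoxb13 lies at 2.98 to 5.60 CPM in bladder and at 0 in ureter.

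Genes of the uroplakin plaque and of umbrella cells, the outermost urothelial layer, were higher in bladder. Of 18 tested members 7 were higher in bladder and 0 in ureter, the same counts adjusted over the list alone (camera adjusted p = 0.000112; adjusted p = 0.0508 with an estimated correlation, and 1.4e-06 to 0.0508 over 19 alternatives). With the rat as a block 5 members were higher in bladder and 1 in ureter. With the smooth muscle score as a covariate the umbrella list had a median log2 fold change of -0.37, against -0.32 without it, and 2 members passed toward bladder and 1 toward ureter. There Upk2 (log2 fold change -0.69 ± 0.21, against -0.86 ± 0.14 without it) and Upk1b (-0.45 ± 0.19, against -0.53 ± 0.12) lost their calls (edgeR adjusted p = 0.0895 and 0.205; 1.92e-09 to 0.135 and 0.000136 to 0.205 over 26 alternatives). Krt20, the keratin of umbrella cells, was at 96.0 ± 20.1 CPM in bladder and 6.95 ± 2.92 CPM in ureter (log2 fold change -3.77 ± 0.29, edgeR adjusted p = 0.000149, n = 4 each). The uroplakins themselves differed less. Upk2 was at 4214 ± 502 and 2325 ± 239.5 CPM, 1.81-fold higher in bladder (edgeR adjusted p = 0.00445), and Psca was 1.93-fold higher. Upk1a, Upk1b and Upk3a were 1.45-, 1.44- and 1.38-fold higher in bladder (edgeR adjusted p = 0.0273, 0.0225 and 0.0421). With the rat as a block, edgeR adjusted p was 0.065 for Upk1a and 0.0762 for Upk3a, and these 2 genes passed in 8 and 7 of 26 alternatives (adjusted p from 9.68e-06 to 0.38 and from 0.000167 to 0.483). Leaving out 1 library ended the call of Upk1a for bladder 1, 3 or 5 and ureter 1, 4 or 5, that of Upk3a for every library except bladder 4, and that of Upk1b for ureter 1 or 4 (edgeR adjusted p up to 0.0849, 0.124 and 0.0715). Upk3b was at 30.3 ± 9.40 CPM in ureter and 43.95 ± 21.99 CPM in bladder (edgeR adjusted p = 0.34).

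Squamous keratinisation genes were also higher in bladder as a group, with 3 of 12 members past the threshold and 0 higher in ureter (4 and 1 adjusted over the list alone). The camera adjusted p was 0.00207, with adjusted p = 0.327 with an estimated correlation, 0.0549 without bladder library 1 and 0.0547 with the smooth muscle score as a covariate (2.04e-07 to 0.327 over 19 alternatives). With that covariate the median log2 fold change of the squamous list was 0.02 instead of -0.31. Krt4, a keratin of stratified mucosal epithelia, was at 219 ± 52.3 CPM in bladder and 7.99 ± 1.29 CPM in ureter (log2 fold change -4.78 ± 0.21, edgeR adjusted p = 5.4e-06, n = 4 each). Evpl, a cornified envelope protein, was 1.70-fold higher in bladder (edgeR adjusted p = 0.00169). Msln, a surface protein of mesothelium, was at 445 ± 113 and 118 ± 13.4 CPM, higher in all 4 bladder libraries (edgeR adjusted p = 0.000294).

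**Figure D2:**
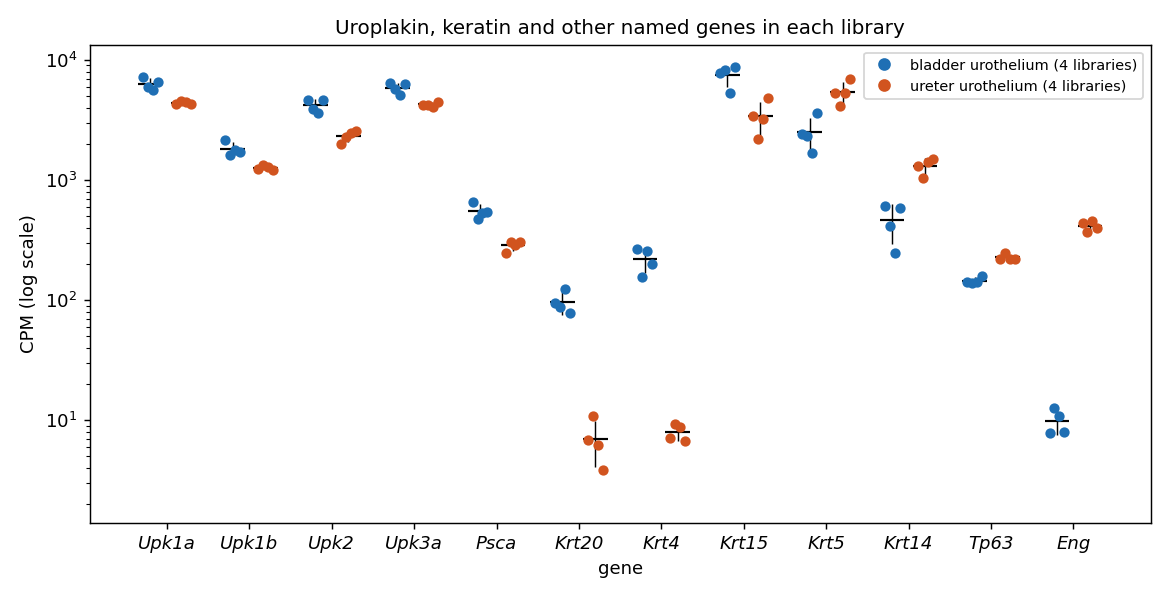
CPM of 12 named genes in each of the 8 libraries on a log axis, with bladder in blue and ureter in orange; horizontal lines are means and vertical lines SD over 4 libraries. Upk2, Krt20 and Krt4 are higher in bladder, Krt14, Tp63 and Eng are higher in ureter, and Krt15 and Krt5 go in opposite directions.

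Basal cell genes went both ways. Of 18 members 5 were higher in ureter and 3 in bladder (7 and 3 adjusted over the list alone), and the list was not past the threshold (camera adjusted p = 0.074), although it was without bladder library 5 (0.0368) or ureter library 3 (0.00372; 0.002 to 0.686 over 19 alternatives). The median log2 fold change of the basal list was 0.247. It was 0.66 with the smooth muscle, 0.37 with the fibroblast and -0.003 with the nerve score as a covariate. Krt14 was at 1313 ± 204 CPM in ureter and 464 ± 169 CPM in bladder (log2 fold change 1.502 ± 0.266, edgeR adjusted p = 0.00737, n = 4 each). Tp63, the basal transcription factor, was at 227 ± 13.3 and 146 ± 9.64 CPM, 1.56-fold higher in ureter (edgeR adjusted p = 0.00172). Cd44 was 1.69-fold higher. Krt5 was 2.18-fold higher in ureter (edgeR adjusted p = 0.0185), a call lost without bladder library 3 or ureter library 4 (adjusted p up to 0.0581 over the fits without 1 library). Other basal genes were higher in bladder: Krt15 by 2.18-fold and Col17a1, a hemidesmosome collagen, by 1.85-fold (edgeR adjusted p = 0.0201 and 0.0204). Both calls were lost without bladder library 3 or 5 or ureter library 1 or 4 (adjusted p up to 0.0679 and 0.0614 over the fits without 1 library). Shh, which basal urothelial cells secrete, was at 62.8 ± 17.5 CPM in ureter and 81.4 ± 25.7 CPM in bladder (edgeR adjusted p = 0.367).

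Cell division genes were higher in ureter: 12 of 26 members passed in that direction and 0 in the other (17 and 0 adjusted over the list alone). Top2a was at 27.2 ± 7.55 CPM in ureter and 9.93 ± 3.56 CPM in bladder (log2 fold change 1.46 ± 0.30, edgeR adjusted p = 0.0161, n = 4 each). Plk1, a mitotic kinase, was 2.63-fold higher in ureter. The camera adjusted p of the cell division list was 4.27e-09, with adjusted p = 0.327 with an estimated correlation (4.07e-14 to 0.327 over 19 alternatives). Its median log2 fold change of 1.19 was 0.98 with the nerve score as a covariate, where 0 members passed. Stem and progenitor genes had 3 of 13 members higher in ureter and 2 in bladder, the same adjusted over the list alone. Aldh1a1, a retinaldehyde dehydrogenase, was at 273 ± 75.8 CPM in ureter and 21.7 ± 5.34 CPM in bladder (3.66 ± 0.25, edgeR adjusted p = 7.81e-05). Prom1 was 2.96-fold higher in ureter. That list passed by camera (adjusted p = 0.00412), with adjusted p = 0.327 with an estimated correlation and 0.0559 without bladder library 1 (0.00155 to 0.327 over 19 alternatives).

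Among further genes with large folds toward ureter was Ttr, a carrier of thyroid hormone and retinol-binding protein, at 126.8 ± 2.35 against 13.8 ± 3.74 CPM (edgeR adjusted p = 1.97e-05, n = 4 each). Ace, Slc1a5 (a glutamine transporter) and Gsta3, a glutathione transferase, were 9.88-, 8.30- and 6.88-fold higher in ureter. Eng itself had a log2 fold change of 5.40 ± 0.19 (edgeR adjusted p = 1.6e-06). Toward bladder stood Slc30a10, a manganese exporter, at 10.8 ± 2.34 against 0.401 ± 0.288 CPM (log2 fold change -4.74 ± 0.45, edgeR adjusted p = 0.000294). Dhrs9, Pla2g2a and Olr1 belong here too, but bladder library 4 held 75.8, 142 and 45.05 CPM of them against at most 3.69, 10.7 and 7.26 CPM in the other bladder libraries. Each kept its call without bladder library 4. Over the fits without 1 library their smallest log2 fold changes were -3.16, -3.48 and -2.72, against -6.37, -6.24 and -4.30 with all libraries. Each lost its call without ureter library 1, 4 or 5, and Dhrs9 and Pla2g2a also without ureter library 3 (edgeR adjusted p up to 0.0947, 0.0748 and 0.0742 over the fits without 1 library). With the rat as a block, edgeR adjusted p was 0.0773 for Dhrs9 and 0.0574 for Olr1 (0.00341 to 0.426 and 0.000346 to 0.594 over all alternatives).

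Of the signalling lists, those of Notch genes and of FGF and EGF genes passed by camera, and neither did so with an estimated correlation. Of 11 Notch genes 6 were higher in ureter and 1 in bladder (8 and 1 adjusted over the list alone; camera adjusted p = 0.00159, with adjusted p = 0.327 with an estimated correlation and 0.173 with the smooth muscle score as a covariate; 0.000161 to 0.327 over 19 alternatives). The median log2 fold change of the Notch list was 0.70 with that covariate and 0.75 without it. Nrarp, a target of Notch, was at 236 ± 93.8 CPM in ureter and 79.0 ± 23.6 CPM in bladder (log2 fold change 1.58 ± 0.30, edgeR adjusted p = 0.0106, n = 4 each). The ligand Jag2 was 1.78-fold higher in ureter. Hes1, also a Notch target, was 2.29-fold higher in bladder, a call lost without bladder 3, 4 or 5 or ureter 1, 4 or 5 (edgeR adjusted p up to 0.0921 over the fits without 1 library). Of 17 FGF and EGF genes 5 were higher in ureter and 1 in bladder (6 and 1 adjusted over the list alone; camera adjusted p = 0.0369, with adjusted p = 0.439 with an estimated correlation, 0.0579 without bladder library 4 and 0.0806 without ureter library 1; 0.00262 to 0.439 over 19 alternatives). By fry the adjusted p of the FGF and EGF list was 0.0564. With the nerve score as a covariate 0 members of it passed, at a median log2 fold change of 0.266 against 0.244 without it. The EGF family ligand Epgn was 7.28-fold higher in ureter, at 3.61 ± 1.82 against 0.50 ± 0.24 CPM (edgeR adjusted p = 0.0112). Fgfbp1, an FGF carrier, was 10.7-fold higher in bladder, at 3.38 ± 2.27 against 0.31 ± 0.11 CPM (edgeR adjusted p = 0.00473). Both calls were lost with the nerve score as a covariate (edgeR adjusted p = 0.127 and 0.054). The log2 fold changes of Epgn and Fgfbp1 hardly moved there, at 2.76 and -3.26 against 2.86 and -3.42 without it. BMP and TGF-beta genes divided 5 and 2 among 19 (5 and 4 adjusted over the list alone, camera adjusted p = 0.264). They divided 4 and 4 with the rat as a block, and 3 and 2 without bladder library 4. Bmp3 was at 83.0 ± 3.99 CPM in ureter and 24.2 ± 6.97 CPM in bladder (edgeR adjusted p = 0.000611), and Tgfb2 was 4.49-fold higher in bladder. Wnt genes divided 4 and 1 among 15 (6 and 2 adjusted over the list alone; camera adjusted p = 0.074, and 0.00907 without bladder library 4; 0.000987 to 0.945 over 19 alternatives). No hedgehog gene of 9 passed over all genes or over the list alone (camera adjusted p = 0.998), and there the median and mean were -0.16 and -0.25 although camera gave an upward direction. With the smooth muscle score as a covariate the hedgehog list was lower in ureter (0.0364; 0.0364 to 0.999 over 19 alternatives).

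Metabolic and defence lists held single genes far apart. Among 19 xenobiotic genes 4 were higher in each tissue (4 in ureter and 5 in bladder adjusted over the list alone). The list did not pass (camera adjusted p = 0.601), but it did with the smooth muscle score as a covariate (0.0438; 0.0438 to 0.918 over 19 alternatives). Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, was at 743 ± 703 CPM in bladder and 35.4 ± 20.7 CPM in ureter (log2 fold change -4.39 ± 0.66, edgeR adjusted p = 0.00332, n = 4 each), with 1797 CPM in bladder library 4 and 377 to 420 CPM in the other bladder libraries (log2 fold change -3.46 without bladder library 4). Cyp1b1 and Aldh3a1 were 20.4- and 15.1-fold higher in bladder (edgeR adjusted p = 0.00285 and 0.000271; log2 fold change of Cyp1b1 -4.35, and -4.94 without ureter library 1). Of 14 retinoid genes 2 were higher in ureter and 3 in bladder, the same over the list alone (camera adjusted p = 0.379). The retinaldehyde dehydrogenases went apart, Aldh1a1 toward ureter and Aldh1a2 toward bladder by 5.81-fold (log2 fold change -2.54, and -1.74 without bladder library 4), and Cyp26a1, which degrades retinoic acid, was 6.91-fold higher in ureter. Of 18 PPAR and fatty acid genes 2 were higher in each tissue (2 and 4 over the list alone; camera adjusted p = 0.383). Fabp4, a fatty acid carrier, was at 1703 ± 191 CPM in bladder and 429 ± 83.6 CPM in ureter (edgeR adjusted p = 0.000152), while Pparg was at 219 ± 51.8 and 262 ± 85.1 CPM (edgeR adjusted p = 0.524). Hypoxia and glycolysis genes divided 3 and 1 among 15 (the same over the list alone; camera adjusted p = 0.962), with the glucose transporter Slc2a1 2.67-fold higher in bladder and Egln3 2.22-fold higher in ureter.

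The lists of tight junction genes (2 higher in ureter and 1 in bladder of 15), transport genes (1 and 2 of 18) and innate defence genes (0 and 1 of 18) were not past the threshold by camera (adjusted p = 0.601, 0.7 and 0.7), and adjusted over the list alone they gave 2 and 1, 1 and 2, and 1 and 2. Wfdc2, a secreted antiprotease, was the innate defence gene that passed, 1.71-fold higher in bladder (edgeR adjusted p = 0.00266). No member of the interferon response (21 tested) or class II antigen presentation list (6 tested) passed over all genes or over the list alone (camera adjusted p = 0.379 and 0.528). Under the fit with the rat as a block 1 interferon member passed toward ureter. With the smooth muscle or fibroblast score as a covariate 3 and 4 passed toward bladder. The median and the mean or the camera direction differed in sign for the retinoid, xenobiotic, innate defence, fibroblast and lymphocyte lists. Of 18 early response and heat shock genes 4 were higher in ureter and 1 in bladder (5 and 1 over the list alone; camera adjusted p = 0.042). That call was lost with an estimated correlation (adjusted p = 0.678) and without bladder library 1, bladder library 3 or ureter library 3 (0.0739, 0.157 and 0.201; 0.00294 to 0.945 over 19 alternatives). With the smooth muscle score as a covariate the early response median was -0.046 instead of 0.352, with 0 members higher in ureter and 1 in bladder. With the nerve score it was 0.45, with 1 and 0 members. Atf3 and Ier3, both induced by stress, were 2.28- and 2.38-fold higher in ureter.

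Markers of other cell types differed between the tissues and among libraries. Smooth muscle markers were higher in ureter (3 of 10 members and 0 in bladder, 4 and 0 over the list alone; camera adjusted p = 0.000356, with adjusted p = 0.494 with an estimated correlation; 2.2e-11 to 0.945 over 19 alternatives), with Myh11 at 53.3 ± 32.5 CPM in ureter and 6.79 ± 3.24 CPM in bladder (edgeR adjusted p = 0.00503, n = 4 each). Endothelial markers were higher in ureter at low levels (4 of 10 and 0, 6 and 0 over the list alone; camera adjusted p = 0.000812, with adjusted p = 0.494 with an estimated correlation; 7.6e-07 to 0.731 over 19 alternatives), with Cdh5 at 2.98 ± 1.03 and 0.721 ± 0.436 CPM. Cdh5 lost its call without bladder library 3 or 5 or ureter library 1 or 4. Its edgeR adjusted p was 0.0217, and up to 0.0671 over the fits without 1 library. Without bladder library 4, 6 of 11 smooth muscle and 7 of 11 endothelial markers passed toward ureter. The rat as a block gave 6 and 5 of 10, and the nerve score as a covariate 1 and 0 of 10. With that score the median log2 fold changes of the smooth muscle and endothelial lists were 2.329 and 2.242, against 1.635 and 1.904 without it. Nerve and glia markers were higher in bladder (4 of 12 and 0, 8 and 1 over the list alone; camera adjusted p = 0.00459, with adjusted p = 0.494 with an estimated correlation; 1.78e-08 to 0.921 over 19 alternatives). Their mean log2 CPM was 5.73, 5.04 and 4.10 in bladder libraries 3, 4 and 5, but 1.402 in bladder library 1, below the 1.52 to 2.58 of the ureter libraries. Neurofilament Nefm and the neuronal transport motor Kif1a, among the largest folds toward bladder (log2 fold changes -8.11 ± 1.34 and -5.53 ± 0.81, edgeR adjusted p = 0.00509 and 0.00282), followed that order, at 0.58 and 1.35 CPM in bladder library 1 and 30.3 and 20.3 CPM in bladder library 3. Both lost their calls with limma-voom (adjusted p = 0.126 and 0.074) and with limma-trend on FPKM without a filter (0.0893 and 0.0822; 1.82e-06 to 0.36 over 23 and 8.63e-14 to 0.164 over 24 alternatives). The log2 fold change of Nefm was -7.43 without bladder library 3 and -9.46 without ureter library 4. The neuronal filament Prph was at 0.96 CPM in bladder library 1 and 23.9 to 80.2 CPM in the other bladder libraries (edgeR adjusted p = 0.0135, and 0.0514 without ureter library 4; 1.14e-05 to 0.873 over 26 alternatives).

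Adipocyte and mesothelial markers were higher in bladder (1 of 3 and 0, 2 and 0 over the list alone). The camera adjusted p was 0.0154, with adjusted p = 0.387 with an estimated correlation and 0.0559 without bladder library 1 (0.000238 to 0.387 over 18 alternatives). Only Msln passed over all genes. Lrrn4 was at 32.4 CPM in bladder library 4 and 0.54 to 1.25 CPM in the other bladder libraries (edgeR adjusted p = 0.0696), and the remaining member went toward ureter. Fibroblast markers gave 0 and 1 of 14 (1 and 1 over the list alone), with a camera adjusted p of 0.559 (5.52e-06 to 0.97 over 19 alternatives). Without bladder library 4 they were higher in ureter (camera adjusted p = 0.00631), with 3 members passing there and 0 in bladder. The median log2 fold change was then 1.056, against 0.008. Bladder library 4 stood highest of all 8 libraries at a mean log2 CPM of 5.88. Red blood cell genes stood at 7.85 in that library and at 1.58 to 2.39 in the other bladder libraries (camera adjusted p = 0.7, and 0.00839 with the smooth muscle score as a covariate; 0.00839 to 0.997 over 16 alternatives). Macrophage and dendritic cell, lymphocyte and striated muscle markers had 0 and 0 of 13, 1 and 0 of 3 and 0 and 0 of 9 members past the threshold, the same over the list alone (camera adjusted p = 0.514, 0.922 and 0.601). The striated muscle list passed with the smooth muscle score as a covariate (0.0438; 0.0438 to 0.963 over 19 alternatives). Mast cell and kidney tubule markers each had 1 tested member, Kit and Lrp2, and no list test. Lrp2, an endocytic receptor of the kidney tubule, was 4.91-fold higher in bladder (edgeR adjusted p = 0.000849), and Kit 2.22-fold (edgeR adjusted p = 0.0341; 0.0727 with the rat as a block, and 0.00723 to 0.303 over 24 alternatives). Kit passed without bladder library 5 or ureter library 5 and was lost without each of the other libraries.

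**Figure D3:**
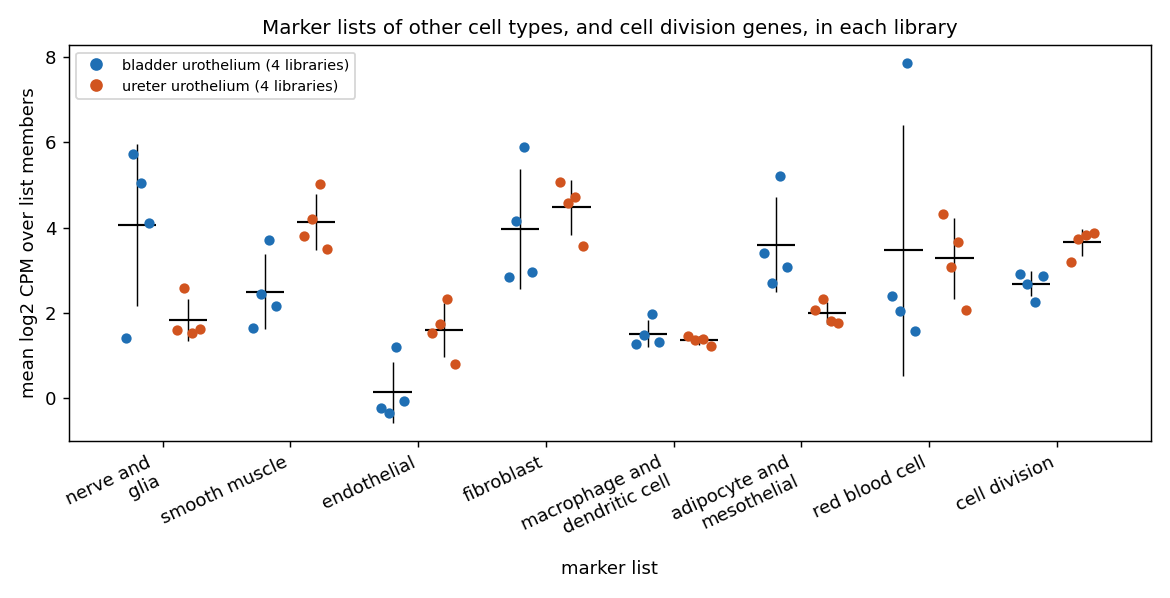
Mean log2 CPM of the tested members of 8 gene lists in each library, with bladder in blue and ureter in orange; horizontal lines are means and vertical lines SD over 4 libraries. Nerve and glia markers are at 1.402 in bladder library 1 and 4.10 to 5.73 in the other bladder libraries, and the red blood cell list reaches 7.85 in bladder library 4.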

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

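The tests on nerve genes by library, on Eng, on basal cells and with the smooth muscle score as a covariate were chosen after the data were seen; the tests on other splits were written beforehand.

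In 27 of 270 groups of 4 libraries (10%) 1 library stood apart, with a gap to the nearest library above Dixon's 95% limit as a share of the group's range, given here in brackets; chance does this in about 1 in 20 groups. Bladder library 4 stood above the other bladder libraries for Sparcl1 (0.936), Dhrs9 (0.966), Pla2g2a (0.938), Cyp1a1 (0.97), Olr1 (0.874), Aldh1a2 (0.884) and Ier3 (0.871), with Aldh1a2 at 71.84 CPM against 15.43 to 21.98 CPM. It also stood above them in the mean log2 CPM of red blood cell (0.871), hedgehog (0.907) and innate defence genes (0.831), and below them for basal cell genes (0.928; 8.237 against 8.572 to 8.598). Ureter library 3 stood apart for Tp63 (0.919), Hoxd3 (0.851), Hoxd11 (1, a single count), Aldh1a2 (0.856), Aqp3 (0.844) and the PPAR (0.832), hypoxia (0.975) and nerve lists (0.905). The remaining ones were Tp63 (0.929) and Egfl7 (0.867) in bladder library 5, Lrp2 (0.834) and the nephric duct list (0.881; 2.056 against 2.956 to 3.078) in bladder library 1, class II genes (0.835) in bladder library 3, Prph (0.831) and Hoxd13 (1, a single count) in ureter library 1, and the posterior Hox list (0.833) in ureter library 5.

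Among the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many genes past the threshold (1513, highest other 1). The same held for genes at least 2-fold apart (676, highest other 1). A chance division is excluded for both only if the libraries are taken as unpaired. Every other split also mixes the tissues within its groups, which adds spread there. Chance cannot be excluded for the number of gene lists by camera at the preset correlation, since 6 of 35 splits gave as many (13; highest other 16). Only 8 of these splits part all 4 rats' libraries, as the real one does, which is too few for a share under 0.05; the highest others among them were 0 genes, 0 genes at least 2-fold apart and 16 lists.

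Nerve and glia genes were high in 3 of the 4 bladder libraries. Expression by bladder urothelial cells in general stays open, since the value against it comes from 1 library. In bladder library 1 the median log2 ratio to the ureter mean was -0.576 (SD over genes 1.148), against 4.833, 4.284 and 3.182 in bladder libraries 3, 4 and 5. Nerve cells carried over into some scrapings have the values they need, since all 9 of the 9 nerve genes with under 10 CPM in ureter had the same order, bladder 3 over 4 over 5 over 1. Of the 371 genes at least 2-fold higher in bladder, 106 were under 2-fold in bladder library 1, and these may hold further genes from such cells. The same count was not made for the other bladder libraries, so the 106 do not by themselves point to nerve cells. A difference in the nerve supply of the tissues stays open and untested.

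Eng was high in all ureter libraries. The values argue against carried-over endothelial cells with equal Eng in both tissues. Eng stood at least 125.1 times above the median endothelial marker in every ureter library, and 6.27 to 18.64 times in bladder libraries. Over the highest endothelial marker it stood 27.1 to 50.18 times in ureter and 1 to 1.523 times in bladder libraries. Endothelial cells with more Eng in ureter were not tested. For fibroblasts or smooth muscle cells carried over the values decide less. Eng over the mean of Col1a1, Col3a1, Acta2 and Myh11 was 26.98 times higher in ureter. That ratio was 1.524 to 5.878 in ureter and 0.01619 to 0.2012 in bladder libraries. Col1a1 and Col3a1, the most abundant of these genes, hardly differed (log2 fold changes -0.17 and -0.41), so the ratio largely repeats the difference in Eng. It argues only against such cells with equal Eng in both tissues. Such cells with more Eng in ureter were not tested. Expression of Eng by ureteral urothelial cells is a hypothesis from these same data; other cell types were not tested.

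Cell division genes were higher in ureter by camera (adjusted p = 4.27e-09), but not with an estimated correlation (adjusted p = 0.327). With the smooth muscle score as a covariate the median log2 fold change was 1.439 times that without it (1.71 against 1.188), and 9 members passed. The median thus did not fall, as dividing smooth muscle cells carried over would have it. The fit cannot decide this, since the score was 3.495 to 5.01 in ureter and 1.643 to 3.711 in bladder libraries and parts poorly from tissue. Without bladder library 4, which had the highest score in bladder, the median was 0.963 with no covariate. Vessel cells had no covariate and were not tested. A larger share of basal cells in the ureter scrapings cannot be told apart, since the basal list's median of 0.247 lay below the cell division quartiles (0.508 to 1.398) while its own quartiles (-0.174 to 0.607) overlapped them. A difference in division between the tissues stays open.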

How the results depend on the processing

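The 3 covariate fits and bladder library 1 alone were chosen after the data were seen. No gene past the threshold passed it in the opposite direction under any alternative. The main counts were 740 genes higher in ureter and 773 in bladder, 305 and 371 at least 2-fold, and 8 and 5 lists. DESeq2 gave 1180 and 1451 genes, and 834 at least 2-fold higher in bladder; without a filter the latter count was 567. Limma-trend on log2(FPKM + 1) gave 168 and 167 genes at least 2-fold apart, and 143 and 143 without a filter. The stricter filter left 3 lists higher in bladder, an estimated correlation 1 higher in ureter and 0 in bladder, and fry 4 higher in ureter and 4 in bladder. By fry the smooth muscle, endothelial, nerve and glia, and early response lists lost their calls (adjusted p = 0.0864, 0.0723, 0.122 and 0.231). The FGF and EGF list lost its call too (0.0564), and the other lists called by camera kept theirs. Without 1 library or 1 rat, 312 to 729 genes were higher in ureter and 318 to 1040 in bladder, 187 to 312 and 201 to 701 at least 2-fold, and 3 to 5 lists were higher in bladder; fewer libraries were then compared. The nerve score as a covariate gave 137 and 210 genes, 103 and 143 at least 2-fold; the smooth muscle score 340 and 444 genes and 8 lists higher in bladder; bladder library 1 alone, whose spread is assumed to be that of the ureter libraries, 48 and 52, and 48 and 49 at least 2-fold. The direction turned for Prph (log2 fold change 0.316) and the nerve list (camera adjusted p = 0.3676) with bladder library 1 alone, and with the smooth muscle score for the hedgehog (0.03641) and fibroblast lists (0.004813); the cause was not tested. Of 93 named genes past the threshold, 58 kept the call in every fit without 1 library, 38 with the nerve score, 61 with the smooth muscle score and 92 with the fibroblast score. The replicate block, the rat, gave 711 and 732 genes and kept 84 of the 93. Besides the calls given in the report it ended those of Lrig1 (edgeR adjusted p = 0.0615), Angptl4 (0.0594), Aqp9 (0.0534) and Cd3e (0.0883), and it changed no other call of a named gene or list. In the simulated counts, where fewer genes changed than passed here, a gene 1.5-fold apart was found in 16% of cases.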

Other observations

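The gene families and single genes in this part were chosen after their values were seen; the camera test on aryl hydrocarbon receptor genes was written beforehand, and the permutation test on them was added afterwards.

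Among single genes chosen after their values were seen, Ccnd1 and Cdkn1c stood apart in all 4 rats. Ccnd1, the cyclin that drives entry into S phase, was at 445.7 ± 48.06 CPM in ureter and 89.34 ± 15.77 CPM in bladder (log2 fold change 2.32 ± 0.14, edgeR adjusted p = 3.6e-05, n = 4 each), whereas Cdkn1c, an inhibitor of cyclin-dependent kinases, was at 14.19 ± 3.62 and 247.4 ± 32.33 CPM (-4.12 ± 0.19, edgeR adjusted p = 6.65e-06). The transcription factors Meis1, a Hox cofactor, and Tbx1 were 11.73- and 6.70-fold higher in bladder (edgeR adjusted p = 0.000942 and 0.000221).

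Some gene families held many genes past the threshold. Of 34 families, 7 passed Fisher's exact test on the share of genes called, at an adjusted p under 0.05. These are the first 7 given below. Small families such as Iroquois genes (2 of 3 called) and aquaporins (2 of 4) did not pass. The families were looked at after the data were seen, so only counts are given and the test adds no support. Of all tested genes 11.6% passed. Hox genes had 11 of 17 (6 higher in ureter and 5 in bladder), and matrix metalloproteases, which cleave extracellular matrix, 8 of 13 (6 and 2). Keratins had 9 of 22 (5 and 4), aldehyde dehydrogenases 7 of 14 (4 and 3), Wnt ligands 4 of 7 (3 and 1), BMP and GDF ligands 4 of 8 (3 and 1) and solute carriers 35 of 195 (13 and 22). Ribosomal protein genes had 8 of 79 (6 and 2).

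More aryl hydrocarbon receptor activity in bladder urothelium was a possible explanation of the higher Cyp1a1, Cyp1b1 and Aldh3a1 there. Of 7 other receptor-responsive genes 4 could be tested, and they went both ways. As a group they did not pass (limma camera p = 0.5704; two-sided exact permutation test on their mean log2 CPM, ureter minus bladder -0.028, p = 0.914). Ahrr, the receptor's repressor and target, was lower in ureter (15.78 against 33.95 CPM, edgeR adjusted p = 0.00293), while Nqo1, Cyp2s1 and Tiparp did not pass; Ahr itself was 1.79-fold higher in ureter (edgeR adjusted p = 0.00238). The bound set in advance, a camera p of 0.05 or more, was too weak to exclude the explanation, because a group of genes that go both ways decides nothing, so it stays open.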
